A study of Homo sapiens with 4 samples.

How the data were processed

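Gene expression was measured in MOLM13, a human acute myeloid leukaemia cell line, after lentiviral transduction with a BTG2 cDNA or with the empty vector. The groups held 2 libraries each, 4 in all, and were assigned from the sample titles. Per the labels' protocols, cells grew in medium with 10% serum, were spin-infected at 32 °C for 60 min at 1500 RCF with 5 µg/mL polybrene, and were collected 3 days later. The vector carried puromycin resistance and ZsGreen, a green fluorescent protein, behind an EF1α promoter, and the labels do not mention selection or sorting. Poly(A) RNA was enriched from about 1 µg of total RNA, per the labels' protocols. The labels' protocols then describe a directional short-fragment kit and paired reads of 150 bp on a NovaSeq X, whereas the series title and design text speak of long reads, and which of these made the values is not given in the sources used here. Per the submitters' processing notes, minimap2 and the hg38 genome build were used, with no version, setting or role.

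The data analysed here are a single table of the authors' own comparison, with 11597 genes and 6 numeric columns, none with a missing value. Its mean column is a non-negative signal, the authors' mean normalized count of each gene pooled over the libraries, per the file headers. Fold changes and their standard errors are on the log2 scale, as deposited by the authors, positive where BTG2 libraries were higher. The deposited test statistic is a score that equals the fold change over its standard error, with a largest difference of 2.72e-07. The deposited p-value is the two-sided normal tail of that score, and the deposited adjusted p-value equals a Benjamini-Hochberg adjustment over the listed genes within 1.48e-06. The program, normalization, gene annotation and filter behind the table are not given in the sources used here. Whether counting used the strand is not given either, so levels of antisense genes and of genes that overlap on 1 strand are uncertain, as are those of genes with near-identical copies.

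Values per library were not analysed here. The depth of each library is therefore unknown, no spread between libraries could be computed, and replicates could not be compared or left out in turn. The labels do not say whether replicates came from separate cultures, so the p-values may measure technical spread alone. Precision followed the mean count. The median standard error of the log2 fold change was 0.13 for genes at or above the median mean count of 151 and 0.32 for genes below it.

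The tests were fixed before the data were examined. With no counts per library, the planned rule for a table of comparisons applied, and a gene was called changed at the authors' adjusted p under 0.05, with no test added. Named genes are BTG2, the 12 largest rises and the 12 largest falls among called genes with a symbol and a mean count at or above the median, and up to 4 members of each described gene list with the largest absolute test statistic. Of 39 gene lists fixed beforehand, the 35 with at least 5 measured members were tested with cameraPR in limma 3.58.1 (R 4.3.3) on the signed score, with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment. The correlation could not be estimated without values per library. Transcript properties came from the longest coding transcript of each gene in GENCODE release 29 on GRCh38, which is hg38. Of the listed genes, 11398 (98.3%) matched that release by Ensembl identifier, and 10402 coding genes other than BTG2 had a complete transcript. Spearman correlations across genes used two-sided permutation tests of 100000 resamples.

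Alternatives fixed beforehand were adjusted p limits of 0.01 and 0.1, a minimum absolute log2 fold change of 1, a test against an absolute log2 fold change of 0.5, genes at or above the median mean count, adjustment over all genes with a p-value, fold changes recentred on the median gene, and an empirical null fitted to the central scores. For lists they were a correlation of 0.05, log2 fold changes in place of scores, ranks, abundant genes alone, and the median against 10000 random lists matched on mean count. Further alternatives were chosen after seeing the data and are named as such in the closing section. Pseudogenes were paired with their closest coding gene by BLAST 2.17.0 over at least 50% of the pseudogene. Intervals of medians came from 10000 or 2000 bootstrap draws of genes at the 95% level. They take genes as independent and measure the spread between genes, not between libraries. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

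The calling, list and correlation steps were tested on simulated data. For the comparison of BTG2 with empty vector, 11597 genes were drawn with the deposited standard errors and 200 of them were changed. The rule called 38.2% of genes changed by 0.5 on the log2 scale, 70.4% of those changed by 1 and 96.7% of those changed by 2, with 9 false calls among 144. These draws took the deposited errors as true, so they cannot test whether those errors are too small. With 200 genes changed there and 940 called in the data, the shares need not carry over. For the lists, all 3 shifted lists were called, with 1 call among the other lists, over 11597 genes. The genes were drawn independently, so the effect of correlation between genes was not tested. For the properties, a seeded relation of 0.1 over 10402 genes came back as a rho of 0.107, and 0 of 5 unrelated properties were called.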

Results

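BTG2 belongs to a family of antiproliferative adaptor proteins that recruit the CCR4-NOT deadenylase to messenger RNA. The design text gives its role in mRNA stability as the question, addressed by overexpressing it in MOLM13 acute myeloid leukaemia cells. Poly(A) RNA was compared 3 days after transduction between 2 libraries with the BTG2 cDNA and 2 with the empty vector. The authors' deposited table lists 11597 genes, with mean normalized counts from 5.06 to 221699 and a median of 151. Values per library were not analysed here, so each error below is the authors' standard error (SE), and how many libraries showed a direction is unknown.

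BTG2 was the gene with the smallest p. It lies on chromosome 1 from 203305491 to 203309602, plus strand, in GENCODE release 29 on hg38. In the authors' deposited table BTG2 (ENSG00000159388.6) rose by a log2 fold change of 5.01 (SE 0.09), or 32.3-fold, at a mean normalized count of 3038, with its adjusted p listed at 0. Reads of the cDNA and of the endogenous gene are not separated in this value. Of its family, BTG1 fell by 0.31 (SE 0.09, adjusted p = 0.00856) in the authors' deposited table, and TOB1 and TOB2 did not pass the test, with log2 fold changes of -0.19 and 0.13. The family list of 5 measured members was called only through BTG2, since its median was -0.19 against a mean of 0.89, and with ranks the limma cameraPR adjusted p was 0.735.

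Beyond BTG2, the transcriptome shifted mostly by small amounts, with genes of the secretory stress response and antigen presentation lower and mitochondrially encoded transcripts higher. Counts assigned to ribosomal protein pseudogenes were higher too, but reads of their parent genes cannot be told from their own. By the authors' deposited table, 940 genes (8.11%) had an adjusted p under 0.05, 422 higher and 518 lower with BTG2. The median log2 fold change was 0.52 among the higher genes and -0.37 among the lower ones, and 820 called genes changed by less than 1. At least 1.5-fold changes were found in 170 higher and 128 lower genes. Besides BTG2, these include 16 higher and 26 lower genes beyond an absolute log2 fold change of 5, whose values do not measure a fold. Recentring on the median abundant gene turned the split to 500 higher and 433 lower, and an empirical null kept 471 genes.

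The largest falls among abundant genes included immune and myeloid genes. HLA-DRA, the alpha chain of an MHC class II molecule, had a log2 fold change of -1.74 (SE 0.18) and its partner HLA-DRB1 one of -1.63 (SE 0.20) in the authors' deposited table. S100P, a calcium-binding protein, stood at -1.70 (SE 0.16) and MPO, the myeloperoxidase of azurophilic granules, at -1.14 (SE 0.15) in the authors' deposited table. C12orf75 (-1.13), the stress-response transcription factor ATF5 (-1.12), the low-affinity IgE receptor FCER2 (-1.12) and MS4A6A (-1.01) followed in the authors' deposited table. The sterol demethylase CYP51A1 (-0.95), PLXNC1 (-0.94), CIB3 (-0.94) and the nuclear DNA sensor IFI16 (-0.91) completed the 12 in the authors' deposited table.

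Among called genes with a symbol and a mean count at or above the median, the largest rises were mostly of pseudogenes and non-coding or mitochondrial RNA. SNORD3A, the U3 small nucleolar RNA that guides ribosomal RNA processing, rose by a log2 fold change of 2.76 (SE 0.21), and the Golgi protein gene GOLGA3 by 1.38 (SE 0.21), in the authors' deposited table. The ribosomal protein pseudogenes RPL17P18 (1.54), RPL10P3 (1.30), RPS2P55 (1.23), RPS7P3 (1.15), RPL13P12 (1.12), RPL32P18 (1.11), RPS15AP1 (1.10) and RPS18P5 (1.02) rose in the authors' deposited table, where reads of their parent genes cannot be told from their own. APOO, which codes for a subunit of the mitochondrial cristae complex MICOS, carried a fitted value of 10.62 (SE 1.46) in the authors' deposited table. It was 1 of 42 called genes other than BTG2 with an absolute log2 fold change above 5, of which 16 were higher and 26 lower. Their mean counts had a median of 14.1, and such fitted values do not measure a fold. Another 73 genes had standard errors from 4.56 to 4.61 with log2 fold changes under 2 in size.

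**Figure D1:**
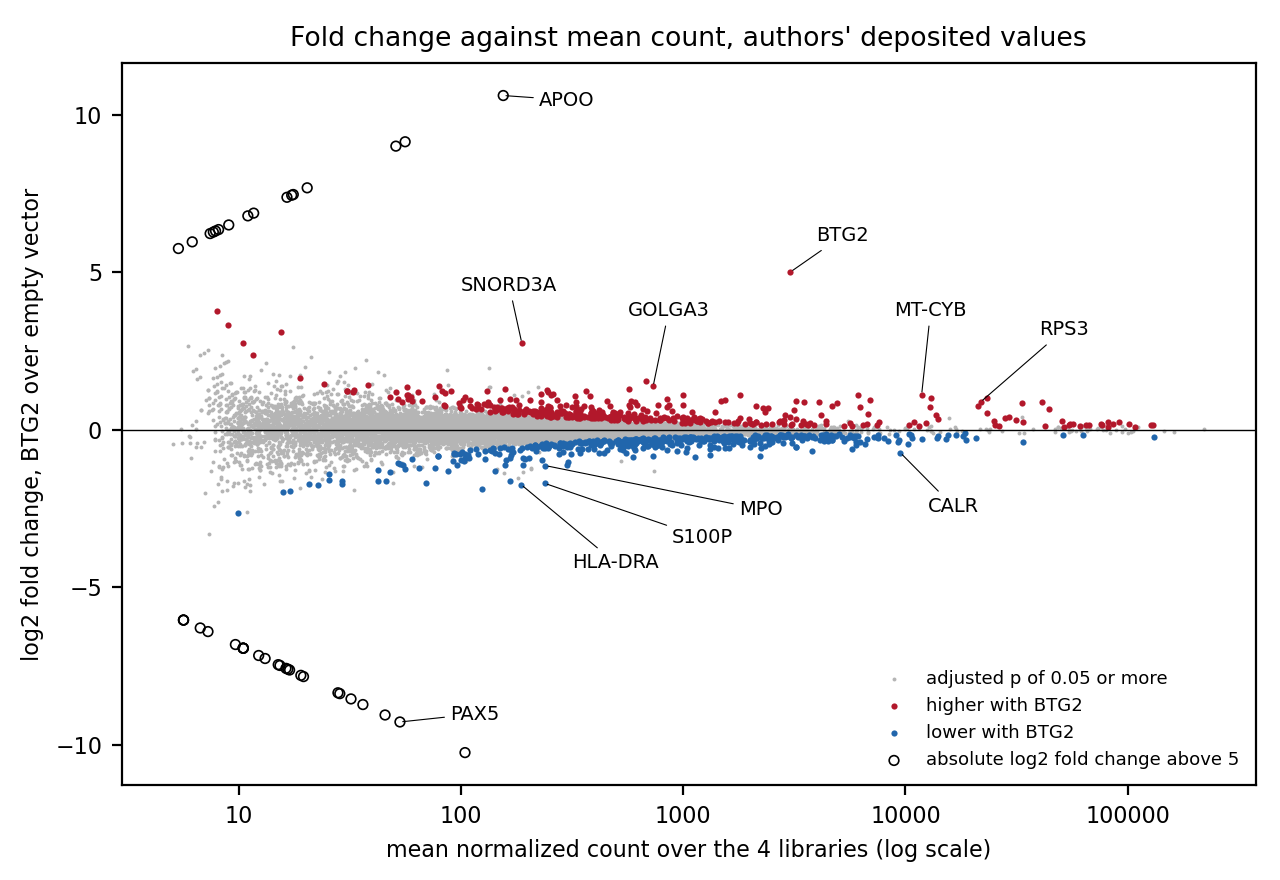
Log2 fold change of BTG2 over empty vector libraries (vertical axis) against the mean normalized count over the 4 libraries (horizontal log axis) for 11597 genes of the authors' deposited table. Red and blue points are the 422 higher and 518 lower genes at an adjusted p under 0.05, except that the 42 called genes beyond an absolute value of 5 other than BTG2 are open circles, and BTG2 stands at 5.01.

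Transcripts of the unfolded protein and integrated stress responses fell together with those of the aminoacyl-tRNA synthetases. In the stress response list 18 of 36 measured members fell and 0 rose, with a median of -0.36, and 21 fell when adjusted over the list alone (limma cameraPR adjusted p = 1.03e-26, from 1.60e-28 to 0.00304 over the alternatives). The endoplasmic reticulum chaperone CALR stood at -0.73 (SE 0.04), the serine synthesis enzyme PSAT1 at -0.83 (SE 0.05), the transcription factor XBP1 at -0.59 (SE 0.04) and the mTORC1 inhibitor DDIT4 at -0.31 (SE 0.03) in the authors' deposited table. All 22 synthetases, the enzymes that charge tRNAs, had negative log2 fold changes with a median of -0.19, and 9 passed the test, or 13 adjusted over the list alone. FARSA (-0.39), GARS1 (-0.47), MARS1 (-0.42) and WARS1 (-0.50) were the clearest of them in the authors' deposited table. The synthetase list had a limma cameraPR adjusted p of 5.99e-10, from 1.44e-10 to 0.338 over the alternatives, where only the test on log2 fold changes missed the threshold.

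Antigen presentation and myeloid lists were lower as well. Of 19 antigen presentation genes 9 fell and 0 rose, or 10 and 0 adjusted over the list alone, with a median of -0.22 (limma cameraPR adjusted p = 8.69e-16, from 8.16e-17 to 0.00700 over the alternatives). Besides HLA-DRA and HLA-DRB1, the class I heavy chain HLA-B stood at -0.40 (SE 0.03) and the class II invariant chain CD74 at -0.56 (SE 0.05) in the authors' deposited table. In the monocyte and macrophage list 8 of 32 members fell and 1 rose, over all genes and over the list alone, with a median of -0.09. The myeloid transcription factor IRF8 (-0.42), lysozyme LYZ (-0.39), the calgranulin S100A8 (-0.73) and the oxidase subunit NCF1 (-0.64) led its falls in the authors' deposited table. Its limma cameraPR adjusted p was 0.000500, from 0.000319 to 0.256 over the alternatives, and the list missed the threshold on log2 fold changes and against matched random lists.

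The granule precursor list held 11 measured genes, of which 5 fell and 2 rose, over all genes and over the list alone, with a median of -0.09. Besides MPO, the protease gene CTSG (-0.49), the granule proteoglycan SRGN (-0.31) and the cystatin CST7 (-0.69) were lower in the authors' deposited table. This list had a limma cameraPR adjusted p of 2.66e-07, from 9.69e-08 to 0.594 over the alternatives, and missed the threshold with ranks, with log2 fold changes and against matched random lists.

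Mitochondrially encoded transcripts rose as a group. All 15 had positive log2 fold changes with a median of 0.75, and 11 passed the test, or 13 adjusted over the list alone (limma cameraPR adjusted p = 6.89e-35, from 1.15e-37 to 0.00140 over the alternatives). Cytochrome b, MT-CYB, rose by 1.12 (SE 0.07), and the complex I subunits MT-ND1 by 1.01 (SE 0.10), MT-ND4 by 0.90 (SE 0.06) and MT-ND5 by 0.80 (SE 0.08), in the authors' deposited table. Nuclear-encoded genes of oxidative phosphorylation were not called as a list, with 2 of 79 higher and 6 lower, or 4 and 7 adjusted over the list alone (limma cameraPR adjusted p = 0.335). Among them ATP5F1B (-0.21) and NDUFS3 (-0.30) were lower and NDUFA7 (0.62) and NDUFA10 (0.62) higher in the authors' deposited table. Mitochondrial ribosomal proteins were not called either, with 5 of 74 higher and 2 lower, over all genes and over the list alone (limma cameraPR adjusted p = 0.633).

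Cytosolic ribosomal protein genes rose modestly. Of 79 members 24 rose and 4 fell, or 29 and 7 adjusted over the list alone, with a median of 0.06 (limma cameraPR adjusted p = 9.57e-14, from 9.66e-15 to 0.880 over the alternatives, the highest on log2 fold changes). RPS3 rose by 0.89 (SE 0.03), RPL10 by 0.46 (SE 0.04), RPLP1 by 0.41 (SE 0.04) and RPL29 by 0.38 (SE 0.03) in the authors' deposited table. Counts assigned to their pseudogenes rose further. Of 117 ribosomal protein pseudogenes with a parent among 58 such genes, 40 were higher and 0 lower at an adjusted p under 0.05. Their median log2 fold change was 0.47 (95% interval across pseudogenes 0.30 to 0.71, with shared parents not allowed for). Of 70 other pseudogenes 5 were higher and 5 lower, with a median of 0.03, but these were not matched on the mean count of the parent. Among the 70, all copies of the parents of highest mean count, EEF1B2 (34323), TMSB4X (33987) and TUBB (15523), had positive log2 fold changes. These were EEF1B2P2 (2.11), EEF1B2P6 (1.25), EEF1B2P3 (0.91), TMSB4XP4 (0.71) and TUBBP1 (0.70) in the authors' deposited table, where EEF1B2P6 and EEF1B2P3 passed the test.

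**Figure D2:**
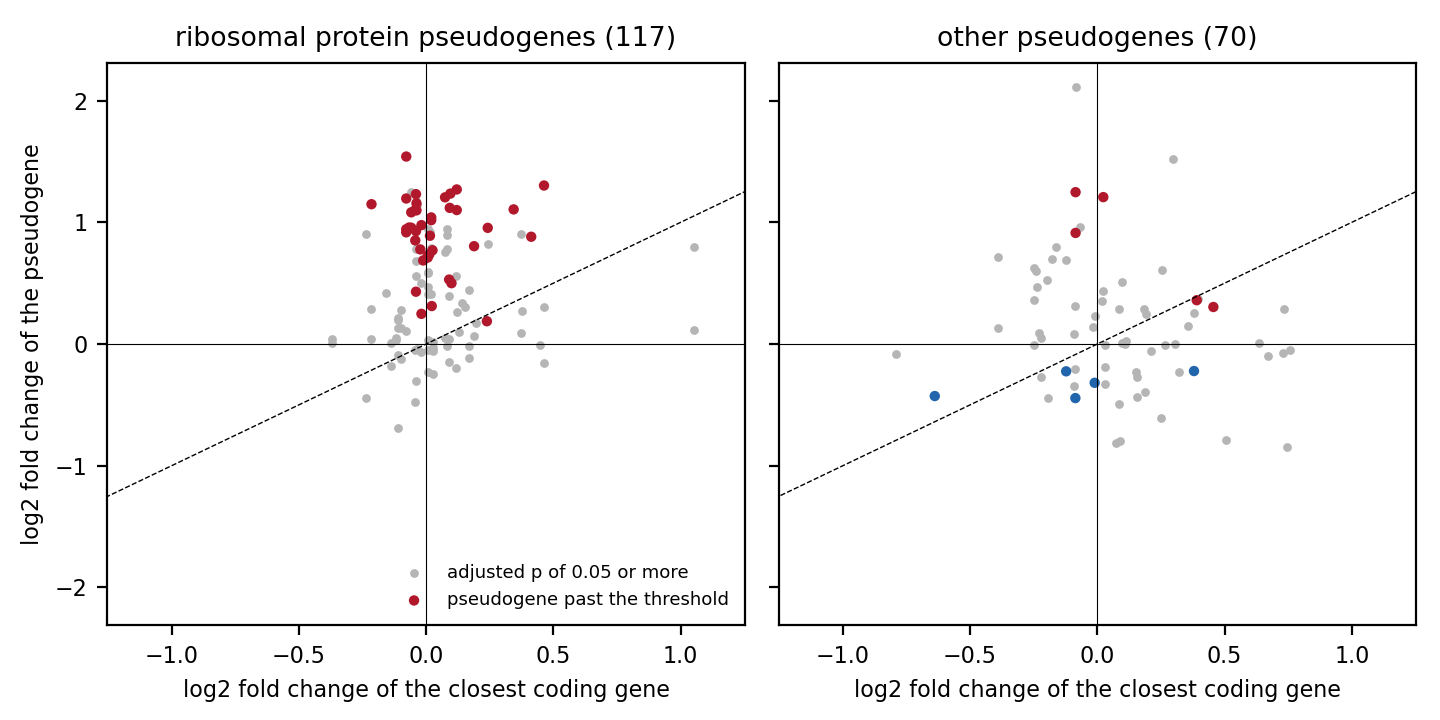
Log2 fold change of each pseudogene (vertical axis) against that of its closest coding gene (horizontal axis), for 117 ribosomal protein pseudogenes on the left and 70 other pseudogenes on the right. Coloured points have an adjusted p under 0.05 in the authors' deposited table, red higher and blue lower, and the dashed line marks equal values; on the left 84 points lie above it.

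Cell cycle, proteasome, interferon and cholesterol lists were called lower too. Of 65 G2/M genes 11 fell and 1 rose, or 15 and 2 adjusted over the list alone, with a median of -0.16. HMGB2 (-0.31), CKS1B (-0.39), the mitotic kinase CDK1 (-0.28) and CKS2 (-0.31) were lower in the authors' deposited table. The G2/M list had a limma cameraPR adjusted p of 0.000599, from 0.000156 to 0.338 over the alternatives, and 0.0655 with a correlation of 0.05. Of 65 G1/S genes 11 fell and 4 rose, or 16 and 6 adjusted over the list alone, with a median of -0.11. UHRF1 (-0.51) and the replication helicase subunits MCM2 (-0.34) and MCM3 (-0.23) were lower, whereas MCM7 was higher at 0.28, in the authors' deposited table. For G1/S the limma cameraPR adjusted p was 0.0163, from 0.00524 to 0.613 over the alternatives, and 0.223 with a correlation of 0.05.

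Proteasome genes fell in 7 of 31 cases and rose in 1, or 11 and 2 adjusted over the list alone, with a median of -0.15 (limma cameraPR adjusted p = 0.000599, from 0.000387 to 0.880 over the alternatives). The core and regulatory subunits PSMA6 (-0.40), PSMA3 (-0.26), PSMB4 (-0.18) and PSMD14 (-0.37) were lower in the authors' deposited table. Of 33 interferon-response genes only HERC5, IFITM2 and BST2 fell, 3 in all and 4 adjusted over the list alone, though the median was -0.36. HERC5 stood at -1.71 (SE 0.53), IFITM2 at -0.25 (SE 0.05) and BST2 at -0.26 (SE 0.07) in the authors' deposited table. The interferon list had a limma cameraPR adjusted p of 0.0163, from 0.00140 to 0.241 over the alternatives, and 0.154 with a correlation of 0.05. Cholesterol synthesis genes fell in 5 of 24 cases, 7 adjusted over the list alone, with a median of -0.17, among them DHCR7 (-0.32) and INSIG1 (-0.23) in the authors' deposited table. Their limma cameraPR adjusted p was 0.0327, from 0.0140 to 0.594 over the alternatives, and 0.168 with a correlation of 0.05.

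**Figure D3:**
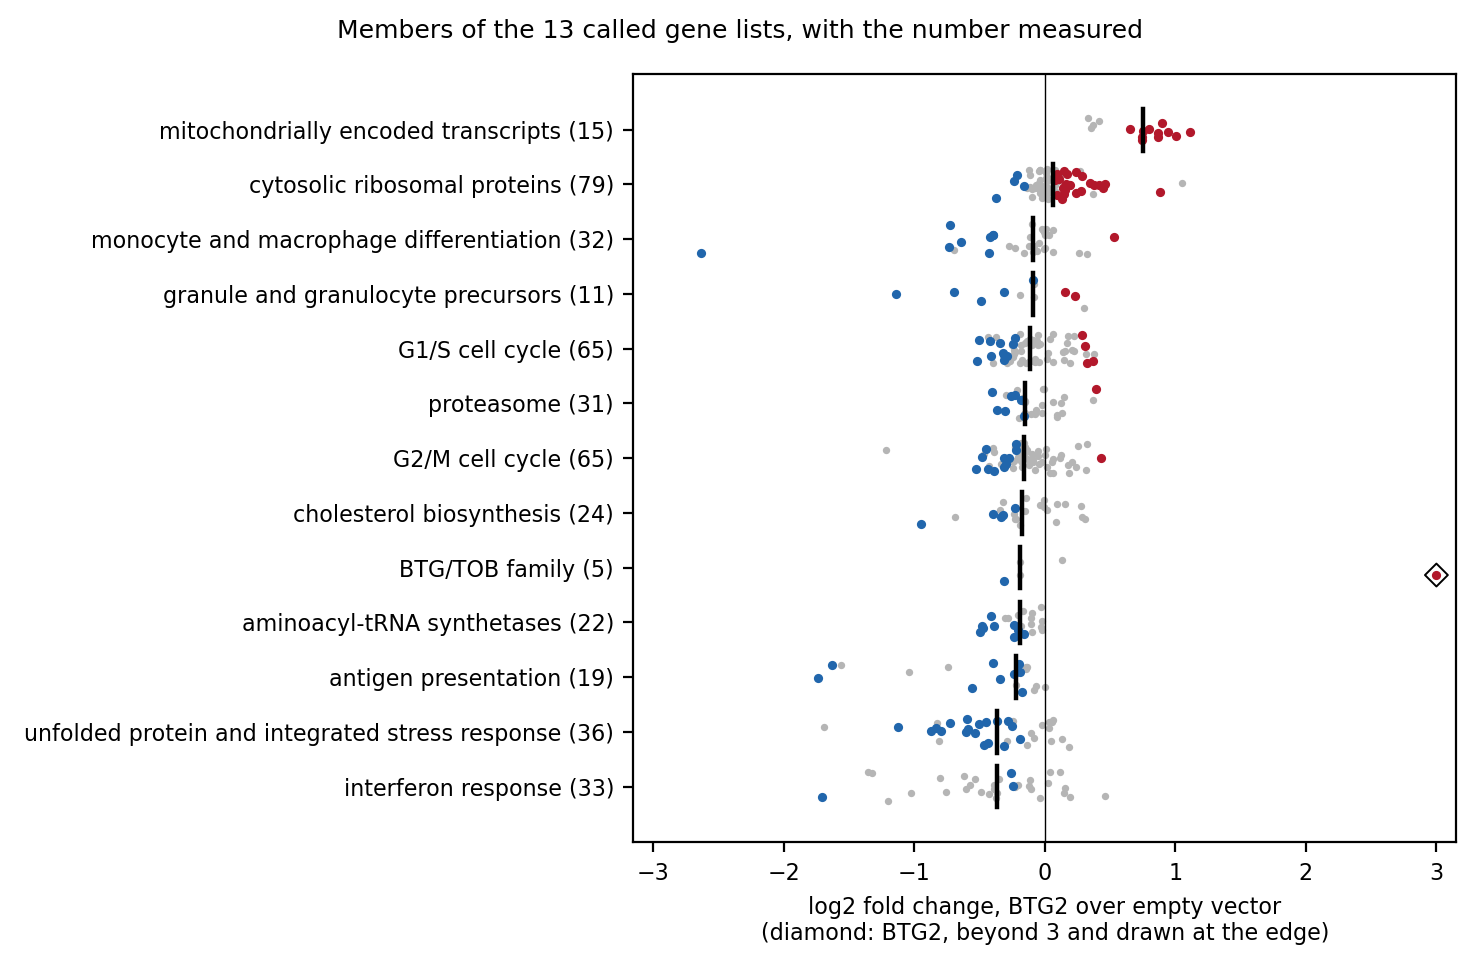
Log2 fold change of BTG2 over empty vector (horizontal axis) for each measured member of the 13 called lists (rows, number measured in brackets). Red and blue points are members higher and lower at an adjusted p under 0.05 in the authors' deposited table, grey points did not pass, and the black bar is the list's median, which is 0.75 for mitochondrially encoded transcripts and -0.36 for the stress response.

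The lists of the mRNA decay machinery were not called as wholes, and the members that passed moved both ways. Of the 16 deadenylase genes 0 were called, over all genes and over the list alone, with a median of -0.06 and a mean of -0.03 although the limma cameraPR direction was up (adjusted p = 0.904). Of 42 decapping and decay genes 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (limma cameraPR adjusted p = 0.497). The decay helicase DDX6 (0.58, SE 0.09) and LSM4 (0.59, SE 0.09) rose and the exosome subunit EXOSC8 (-0.25, SE 0.07) fell in the authors' deposited table. Of 19 genes for proteins that bind poly(A) or AU-rich elements 3 rose and 3 fell, or 5 and 3 adjusted over the list alone (limma cameraPR adjusted p = 0.140). The poly(A)-binding protein gene PABPC1 rose by 0.48 (SE 0.10) and its intronless copy PABPC3 by 0.73 (SE 0.04) in the authors' deposited table, which gives the copy the higher mean count, 12850 against 2877. Of 34 immediate-early and AU-rich transcripts 4 fell and 1 rose, or 6 and 1 adjusted over the list alone, with a median of -0.12 (limma cameraPR adjusted p = 0.127, and 0.0467 against matched random lists, up to 0.642 over the alternatives). The cytokine gene TNF (-0.71), the decay factor ZFP36 (-0.25) and JUNB (-0.26) were lower and FOSL2 (0.38) higher in the authors' deposited table.

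Fold changes were weakly related to transcript properties, computed across 10402 genes, which are not independent replicates. Each property was taken alone, with no joint analysis, so relations with properties that go together are not separated. Of 6 properties tested, log2 fold change rose with 3′ UTR length (Spearman rho 0.133), coding length (0.139) and transcript GC content (0.0616). It fell with mean count (rho -0.101). For AUUUA motifs per kb of 3′ UTR the rho was -0.0578 without a steady fall, since the median was -0.05 both in the 2601 genes of lowest density, with 0 motifs, and in the 2601 of highest density, and 0.01 and 0.00 in the groups between. Each of these 5 had a permutation p of 1e-05, the smallest that 100000 resamples can give, and a Benjamini-Hochberg adjusted p of 1.2e-05. The relation with 5′ UTR length had a rho of 0.00359 (permutation p = 0.716, adjusted p = 0.716). In the 2601 genes with the shortest 3′ UTRs, 1 to 512 bases, the median was -0.06, with 83 genes higher and 210 lower. In the 2601 with the longest, from 2648 bases, the median was 0.04, with 71 higher and 60 lower.

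The remaining lists for this cell line were not called, with limma cameraPR adjusted p from 0.119 for replication-dependent histones, which were called higher on log2 fold changes (1.83e-08) and against matched random lists (0.0356), to 0.851 for ribosome biogenesis and MYC targets. In the list of KMT2A-rearranged leukaemia genes 4 of 25 were higher and 2 lower, or 6 and 2 adjusted over the list alone, among them MYB (-0.27) and CEBPA (-0.26) below and SATB1 (0.35) and PBX3 (0.45) above 0 in the authors' deposited table. RUNX1, a haematopoietic transcription factor, rose by 0.42 (SE 0.10) and was the only one of 6 RUNX family and partner genes to pass in the authors' deposited table. Of 27 p53 targets MDM2 (0.52) and DDB2 (0.36) rose and 0 fell in the authors' deposited table, and CDKN1A, at -0.15, did not pass; adjusted over the list alone 2 rose and 1 fell. Among 20 replication-dependent histone genes H2AC12 (3.10), H4C9 (2.77) and H3C12 (3.33) rose in the authors' deposited table, at mean counts of 15.4, 10.5 and 8.96, and 4 rose adjusted over the list alone. Glycolysis and hypoxia genes moved both ways, with 3 of 30 higher and 2 lower, or 4 and 3 adjusted over the list alone, with GPI at 0.70, ENO1 at 0.79 and TPI1 at 0.73 but PGAM1 at -0.26 in the authors' deposited table. Mean counts were 569 for ENO1 and 169 for TPI1. GAPDH had a lower mean count than its pseudogene GAPDHP1, 40.2 against 117. Whether reads of such genes were assigned to copies was not tested. MYC, in the ribosome biogenesis list of 53 genes with 2 higher and 2 lower over all genes and over the list alone, fell by 0.13 (SE 0.05, adjusted p = 0.0441) in the authors' deposited table, a call lost with recentring and with the empirical null.

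Members of several other lists that were not called moved both ways. Of 43 translation factor genes 5 rose and 4 fell, over all genes and over the list alone, with EEF2 at 0.19 and EIF3C at -0.44 in the authors' deposited table. The cytokine and NF-κB list had 1 of 25 higher and 5 lower, or 2 and 5 adjusted over the list alone, with TGFB1 at 0.75 and NFKB2 at -0.77 in the authors' deposited table. Of 14 heat shock chaperones HSPB1 (-0.39) and HSPA8 (-0.30) fell and HSP90AA1 (0.14) rose in the authors' deposited table, with the same counts adjusted over the list alone. Of 27 apoptosis regulators BIK (-0.54) and PMAIP1 (-0.42) fell and 0 rose in the authors' deposited table, 1 of them adjusted over the list alone. Among 18 genes of cytarabine handling and drug efflux NME1 (0.36) rose and the topoisomerases TOP2A (-0.22) and TOP2B (-0.35) fell in the authors' deposited table, or 2 and 5 genes adjusted over the list alone. Of 21 quiescence genes GAS6 (0.22) rose and CCNG2 (-0.66) and CDKN1B (-0.30) fell in the authors' deposited table, or 1 and 3 adjusted over the list alone. The spliceosome list had 2 of 44 higher and 4 lower, over all genes and over the list alone. Of 13 stem and progenitor genes 0 rose and 1 fell, LAPTM4B at -0.18 in the authors' deposited table, or 1 and 2 adjusted over the list alone. Of 29 lysosome and autophagy genes 0 were called, over all genes and over the list alone.

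Markers of other cell types were sparse. For lymphocytes, NCAM1 (-0.53) and NKG7 (-0.36) were lower among 4 measured T and NK genes, and PAX5 (-9.28) and BLNK (-1.41) were both lower of 2 B cell genes in the authors' deposited table, PAX5 being among the 42 genes without an interpretable fold. Of 2 megakaryocyte genes NFE2 rose by 0.38 (SE 0.12), and 0 of 3 erythroid genes passed in the authors' deposited table. These lists had too few members for a test. The list of 7 epithelial or embryonic-kidney markers, with 0 called, had a limma cameraPR adjusted p of 0.555.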

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

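Alternatives chosen after seeing the data were leaving out nearly absent genes and pseudogenes, keeping protein-coding genes only, leaving BTG2 out of the lists, and, for transcript properties, APPRIS principal transcripts and leaving out ribosomal protein and mitochondrial genes. The number of changed genes moved with the threshold: from 940 it went to 622 at an adjusted p under 0.01, to 120 with an absolute log2 fold change of at least 1, to 81 against a minimum of 0.5 and to 471 with the empirical null, whose spread of 1.25 exceeded that of a standard normal. The stricter limits on p and on fold passed fewer genes by construction. The 120 hold all 42 called genes other than BTG2 beyond an absolute log2 fold change of 5, and the 81 hold 37 of them. Their fitted values do not measure a fold. The empirical null is not stricter by construction. It lost calls because the scores spread more widely than the simulated ones, whose spread was 0.994. The source of this excess was not tested. Each of these sets lay within the 940. The count stayed between 829 and 1223 in the other settings, with 846 genes left without the nearly absent genes and pseudogenes. Recentring raised each log2 fold change by 0.03, shared 855 calls with the deposited values and turned the direction of 0 named genes; BTG2 stood at 5.04. In place of 13 called lists, log2 fold changes gave 6, of which 5 were among the 13 and the other was that of the histones (adjusted p = 1.83e-08). A correlation of 0.05 gave 9, matched random lists gave 12, of which 10 were among the 13, the other settings gave 10 to 12, and 3 lists kept their call and direction throughout, those of mitochondrially encoded transcripts, the stress response and antigen presentation. The BTG/TOB family list turned to lower and lost its call with ranks (adjusted p = 0.735) and against matched random lists (0.161), where BTG2 counts as a single member. The 5 called relations with transcript properties kept their sign and call in every alternative. Of 133 called named genes, 124 were abundant enough for the abundance filter, and 99 of these kept their call under recentring, the empirical null and that filter together. A change of 0.5 was called in 71.9% of simulated genes at or above the median mean count and in 8.33% of those below it, which limits what the table shows for rare transcripts. No paired analysis was possible because values per library were not analysed here. For the same reason other count models, size factors and count filters, replicates left out in turn and an estimated inter-gene correlation were not run, nor were MANE transcripts, which release 29 does not mark.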

Other observations

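Gene groups in this paragraph were chosen after their values were seen, and each value is from the authors' deposited table. All 5 measured metallothioneins, which bind zinc and copper, fell, with a median log2 fold change of -0.65 and MT1X at -0.80 (SE 0.08) in the authors' deposited table. Of 10 S100 genes 6 fell and 0 rose, among them S100A1 (-1.62), S100A9 (-0.72) and S100A4 (-0.23) in the authors' deposited table. The MHC split by class, with 3 of 6 class II genes and 4 of 10 class I genes lower, and medians of -1.15 and -0.20 in the authors' deposited table. The class II median lies between HLA-DMA (-0.74) and HLA-DMB (-1.56, at a mean count of 8.29), neither of which passed. The difference between the classes was not tested. Of 12 host transcripts of microRNAs 4 rose and 0 fell, and the group was not tested against other non-coding genes; higher were those of miR-142 (MIR142HG, 0.78), miR-223 (MIR223HG, 0.77) and let-7b (MIRLET7BHG, 0.84) in the authors' deposited table.

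In the tests below, those of members without an overlap, of chance zeros, of genes missed in 2 libraries, of a fixed rate of shared reads, of drift with mean count and of RNA without a tail were chosen after seeing related values, and the others before. Transcripts of snoRNA host genes were tested as a group that might move together. Of 26 such genes 9 rose, including SNHG9 (0.93), SNHG19 (0.92) and GAS5 (0.24), and 0 fell in the authors' deposited table. Their median of 0.23 lay within the central 95% of lists of other non-coding genes matched on mean count (-0.03 to 0.32), so by its median the group did not stand apart from non-coding RNA. The share called higher was larger than the 32 of 628 among all long non-coding genes, a set not matched on mean count. ATF4, the transcription factor behind many genes of the stress response list, was tested as a candidate source of that list's fall. It stood at -0.19 (95% interval -0.26 to -0.11, adjusted p = 4.58e-05) in the authors' deposited table, against a list median of -0.36. This fall is in the direction the hypothesis needs, although ATF4 is controlled largely at translation, which these data do not measure. The call alone cannot show a source, since among the 2899 genes of highest mean count 368 were called lower and 229 higher.

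The first pattern is the set of 42 called genes with an absolute log2 fold change above 5, such as APOO and PAX5. Chance zeros at low depth stay open, since 37 of the 42 passed a test against 0.5 but were chosen for large folds, and the depth of each library is unknown. Reads assigned to an overlapping gene on the same strand stay open as well. In the GENCODE release used here, 23 of the 38 annotated members overlapped no such gene. The other 15, or 39.5%, overlapped one (exact 95% interval 24.0 to 56.6, against a median of 34.2% in matched lists). The authors' annotation and use of the strand are unknown. Members without an overlap in that release may therefore have had one when reads were counted. A candidate explanation is that a gene can go missing in any 2 of the 4 libraries: 73 genes with standard errors above 4 and small fold changes, with a median mean count of 14.3, look like genes missed in 1 library of each group, and the 42 make up 36.5% of both sets (exact 95% interval 27.7 to 46.0) where groupings at random give 33.3%. Most of the 42 may then owe nothing to BTG2, a reading that rests on the errors alone, and a true loss of single genes among them stays open.

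The second pattern is the rise of ribosomal protein pseudogenes beyond that of their parents, of which 15 of 58 rose and 4 fell, with a median log2 fold change of 0.03. A fixed rate of parent reads is argued against by a median difference from the parent of 0.44 (95% interval across pairs 0.31 to 0.60), and a preference for short transcripts by the median of -0.072 (95% interval across genes -0.09 to -0.03) of 367 short coding genes. More frequent misassignment of parent reads in the BTG2 libraries cannot be told apart from a rise of the pseudogenes themselves, although the rise was larger at lower identity to the parent (Spearman rho -0.37, permutation p = 7e-05), which by the bound set down beforehand would exclude misassignment. That bound was set aside only after the result was seen, because the mean count relative to the parent rose with identity (Spearman rho 0.56, 95% interval 0.40 to 0.71). Some copies at 100% identity exceeded their parents in mean count, such as RPL36AP37 (56821 against 179 for RPL36A) and RPL21P16 (32433 against 664 for RPL21). In such pairs the parent's fold change may not be its own. Near-identical copies may thus hold parent reads in both groups and gain the smaller fold from extra misread bases, which were not measured here. The parents' median mean count of 51498 against 107 leaves ample reads for misassignment, and PABPC3, listed above PABPC1 in mean count, may be a like case. Copies of EEF1B2, TMSB4X and TUBB, the most abundant parents of the 70 other pseudogenes, had positive log2 fold changes too.

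The third pattern is the rise of mitochondrial transcripts beside a small upward shift of long non-coding RNA, of which 32 of 628 genes rose and 3 fell. Drift with mean count is argued against by the median of 0.19 of the long non-coding genes (95% interval across genes 0.15 to 0.24), above the highest of 10000 matched lists of coding genes, 0.08. More RNA without a poly(A) tail in the BTG2 libraries could account only for members of this pattern that lack such tails. Tails were not measured here. For members without them, this source cannot be told apart from a response of the cells. The bound of 0.38 was set from the mitochondrial median of 0.75. The 14 spliceosomal and related small RNA genes had a weighted mean of 0.012 (95% interval -0.20 to 0.23), wholly below that bound, which alone would exclude this source. That mean rests largely on SCARNA9, and without it, a step taken after the result was seen, it was 0.24 (-0.09 to 0.56). Other RNA without such tails had positive medians, 0.43 for 20 histone genes (3 higher, 0 lower) and 0.94 for 4 ribosomal RNA genes (0 called). Of the histone genes 6 had negative log2 fold changes, and the 3 called had mean counts from 8.96 to 15.4. Of 4 small nucleolar RNA genes 2 were higher and 0 lower. However, shorter tails on cytoplasmic mRNA under BTG2, and so weaker capture of those mRNAs than of other RNA, could give the same picture. A true rise of these transcripts could do so as well, and neither was tested.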
